A study of Mus musculus with 8 samples.

How the data were processed

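RNA was measured in cortical bone, the dense outer shell of bone, from 8 C57BL/6J mouse samples. Per the labels, 4 samples carry floxed Ripk4 alleles alone (control) and 4 also carry a ubiquitin C promoter driven Cre recombinase fused to a modified estrogen receptor (KO), a form of Cre that works only once the receptor is bound by its drug. The labels give 4 weeks without saying whether this is an age or a time after induction, and a drug treatment is not given in the sources used here. Total RNA was extracted with Trizol and the libraries were sequenced on an Illumina NovaSeq, per the labels' protocols.

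The authors deposited 1 table of 55401 genes with an estimated count and an FPKM value (fragments scaled by gene length and library size) for each gene and library. HISAT2 2.0.4, StringTie 1.3.4d, DESeq2 and the build GRCm38 are named without a role, per the submitters' processing notes. The tool that made the counts, its strand setting and its filters are not given in the sources used here. Of the table's gene identifiers, 55141 were found in GENCODE M21 (GRCm38), and 51957 of these, 94.23%, had the same coordinates there. The deposited estimated counts are whole numbers, so rounding changed none of them. Low values pile up at 4, 8 and 12 (5609 values of 4 against 2362 of 3), so 1 fragment was taken to be worth about 4 counts. Values of 1 (4234) and 2 (2912) were also common, so this factor is only approximate. The deposited FPKM values are 0.0001 where the count is 0, and the FPKM per count of a gene varied between libraries by a median coefficient of variation of 0.17% after library scaling. All 8 libraries were mapped to columns by name, and 0 columns of sample values were left unused.

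Total counts ran from 61092688 to 66774693 per library, and by that reading the number of fragments is smaller by a factor of about 4. A level resting on at most 3 fragments, or 12 counts, in every library was treated as not measurable, and no fold change is given for it. This floor covers counting error only. The smallest chi-square per degree of freedom between any pair of libraries was 26.8, so no pair was a duplicate within sampling noise.

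Before the data were examined, the comparison, the gene lists, the rule for named genes and most of the alternatives were fixed; additions are named as chosen after seeing the data. That design assumed FPKM values and named limma for them, with edgeR in its place if the table held counts. Since it does, the main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and filterByExpr at a minimum count of 10, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. It tested 20152 genes. Ripk4 and Mfn2 were also compared by a two-sided exact permutation test of log2(FPKM + 0.5) over all 70 assignments of the 8 libraries, which cannot go below p = 0.0286.

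Gene lists fixed beforehand numbered 29, with 16 programmes and 13 sets of cell type markers. Each list with at least 5 tested members was tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry. The score of a list in a library is the mean over members of the centred log2 CPM (counts scaled to library size). Ddit3 has 2 rows in the table, of which the first was used. Bone terms were the Gene Ontology terms in the table's own annotation whose names hold ossif, osteo, bone, mineraliz or skelet, with 5 to 500 tested members. The annotation cell of 2304 genes, 1972 of them tested, reads as removed, so term memberships are incomplete. All Gene Ontology and KEGG terms of 10 to 200 members were tested after seeing the data.

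The named genes are Ripk4 and Mfn2, the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 1 FPKM and groups that do not overlap, and up to 4 members per list with the smallest p. Predicted genes without a proper name and antigen receptor segments were left out. This rule named 133 genes, of which 70 passed. The text and the alternatives take 73 of them, chosen after their values were seen and mostly from those that passed (66). The text alone also gives Ccr2, Ly6c2 and Cd14, which did not pass. Genes outside the rule are said to be chosen after their values were seen. On simulated counts with 200 changed genes among 20152, for the comparison of KO with control, the test recovered 1.49% of 67 genes changed 1.5-fold, 16.4% of 67 changed 2-fold and 50% of 66 changed 4-fold, with 3 false calls. With so few changed genes the adjustment is stricter than in the data, where 2083 genes were called, so these rates need not hold there. On simulated data, 1 risen list was called and 0 of 20 unchanged ones were. Genes were simulated independently of each other, so this cannot tell how often unchanged lists are called when their members vary together.

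The alternatives were other pseudocounts, filters and scalings, limma on FPKM, DESeq2 1.42.0, robust estimation, library weights, the replicate number as a block, and each library left out in turn. Alternatives chosen after seeing the data were counts divided by 4, a muscle score as a covariate, bone terms without those naming the cytoskeleton or muscle, and the omission of libraries that stood apart. The labels do not say that samples are separate animals, so p-values measure the spread between these samples, which may be partly technical.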

Results

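Gene expression was measured by RNA sequencing in cortical bone of mice with floxed Ripk4 alleles, 4 libraries without Cre (control) and 4 with a broadly expressed inducible Cre (KO). Ripk4 encodes a receptor-interacting serine/threonine kinase, and the series title places it in bone-forming lineage cells, acting through Mfn2, a mitochondrial fusion protein. Each library held 61092688 to 66774693 estimated counts over 22818 to 24525 genes above 0. The first principal component held 36.5% of the variance and had all 4 control libraries on one side, from -76.4 to -30.2, and all 4 KO libraries on the other, from 7.56 to 132, with KO 4 the farthest. Transcripts of the mitochondrial genome took 16.1% of the counts in control 3, 11.7% in control 4, 9.21% in control 2 and 5.56% to 6.17% in the other 5 libraries. Transcripts of blood cells were abundant, with a control mean of 16900 FPKM for S100a9 and 7660 for Hbb-bs, against 2050 for Col1a1. The share of blood or marrow cells in the pieces was not measured, so a difference in it between the groups stays open.

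Ripk4 (ENSMUSG00000005251, GRCm38 chromosome 16, 97741933 to 97763787, minus strand) was at the limit of detection in both groups. The estimated counts were 10, 4, 0 and 4 in control 1 to 4 and 0, 12, 0 and 0 in KO 1 to 4, none above the floor of 12 counts. No fold change is given, and no difference between the groups was detected (two-sided exact permutation test, p = 0.657, n = 4 per group). A loss of Ripk4 was not detectable at this depth, so the gene's level does not check the genotype labels.

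Mfn2 (ENSMUSG00000029020, chromosome 4, 147873599 to 147904704, minus strand) was well expressed and did not differ beyond the spread. Its level was 17 ± 1.55 FPKM in control and 19.1 ± 2.62 FPKM in KO (SD, n = 4 each), a log2 fold change of 0.19 ± 0.12 (SE) with an edgeR adjusted p of 0.328. The 95% confidence interval ran from 0.946-fold to 1.38-fold, and the exact permutation test gave p = 0.229. Of 24 genes of mitochondrial dynamics, 1 rose and 0 fell (1 and 0 adjusted over the list alone). The riser was Fis1, an outer membrane fission factor, at 42.3 ± 4.65 FPKM in control and 58.2 ± 4.03 in KO (log2 fold change 0.49 ± 0.09, adjusted p = 0.0178); the call was lost without control 2, control 4 or KO 3 (adjusted p up to 0.0585). The list's median log2 fold change was -0.07, while its camera direction was up, with an adjusted p of 0.751.

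Among genes that met the naming rule, which asks for a mean of at least 1 FPKM and groups that do not overlap, the largest falls in KO included genes of bone matrix and cartilage collagens, and the largest rises included a family of cysteine protease inhibitors and the Mir142 locus. Bglap, which encodes osteocalcin (chromosome 3, 88383501 to 88384464), fell from 563 ± 314 to 26.7 ± 7.45 FPKM, a log2 fold change of -4.42 ± 0.46 with an edgeR adjusted p of 0.00351. Col1a1, the main collagen chain of bone (chromosome 11, 94936224 to 94953042), fell from 2050 ± 852 to 197 ± 118 FPKM, a log2 fold change of -3.38 ± 0.49 with an adjusted p of 0.00889. Tnpo1, a nuclear import receptor (chromosome 13, 98839019 to 98926384), rose from 1.22 ± 0.253 to 8.25 ± 0.743 FPKM, a log2 fold change of 2.80 ± 0.15, and had the smallest p of all tested genes (adjusted p = 0.000561). At an adjusted p under 0.05, 1070 genes rose and 1013 fell, 2083 of 20152 (10.3%), and 5657 genes had an unadjusted p under 0.05. At least 2-fold changes among the called genes were 256 rises and 544 falls. The groups did not overlap for 4169 genes, or 20.7%, where chance gives 2.86%. The count was 791 without control 2, 805 without control 3, 769 without control 4 and 769 without KO 3, and 4189 with DESeq2. It was 1323 with control 3 and KO 4 left out and 23 with control 3, control 4 and KO 2 left out, omissions chosen after seeing the data. Such omissions shrink the groups, which can by itself lower the count. With a muscle score as a covariate, also chosen after seeing the data, the count was 1469.

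The 10 largest falls by the naming rule included genes of bone matrix, cartilage collagens and enzymes. Beside Bglap and Col1a1 they were Bglap2, a second osteocalcin gene (log2 fold change -4.35), Lipc, hepatic lipase (-4.26), Cpz, a carboxypeptidase (-3.99), Prss35 (-3.90), Col11a1 (-3.77), Cthrc1 (-3.55), Col2a1, the main collagen of cartilage (-3.53), and Col11a2 (-3.37). Bglap and Bglap2 are near-identical neighbours that can share reads, so how the fall divides between them is uncertain. Of these 10, Cthrc1 lost its call without KO 3 (edgeR adjusted p at most 0.0507), and the other 9 passed with any 1 library left out.

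**Figure D1:**
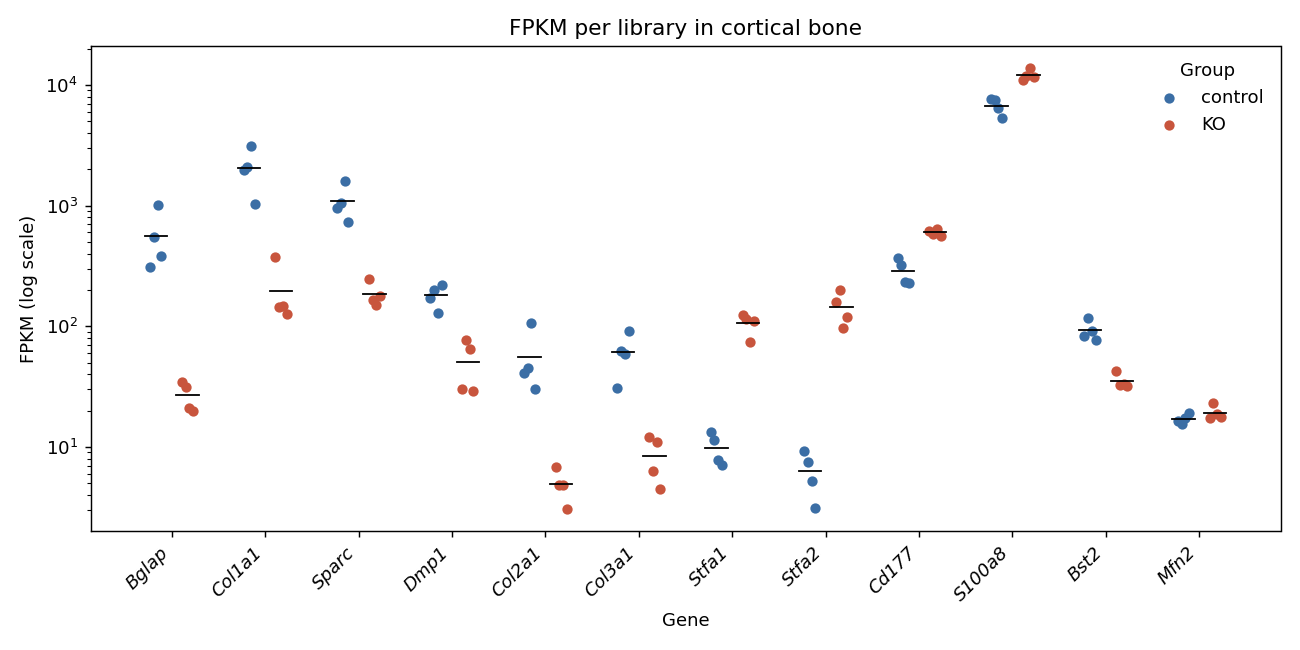
FPKM of 12 named genes in each library (points, log axis), with the group mean as a bar, for 4 control and 4 KO libraries. Bglap lies between 310 and 1010 FPKM in control and between 19.7 and 34.5 in KO, while Mfn2 spans 15.4 to 19 and 17.2 to 22.9.

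Osteoblast genes, which build and mineralise bone matrix, were lower as a group. Of 22 members 12 fell and 0 rose (19 fell when adjusted over the list alone), with a median log2 fold change of -1.80. The fall was uneven, with 19 members lower and 3 higher by fitted fold change. The higher ones were Spp1 (0.02), Mmp13 (0.19) and Phospho1 (0.61), and Runx2 was lower (-0.62). None of these genes, chosen after their values were seen, passed. Sparc, a matrix glycoprotein, fell from 1080 ± 362 to 185 ± 42.6 FPKM, and Col1a2 from 906 ± 371 to 100 ± 37.8. The list passed camera at the preset correlation (adjusted p = 1.1e-19), but not with an estimated one (adjusted p = 0.0814 with an estimated correlation). The osteoblast score was lower in every KO library than in every control library, -1.73 to -0.53 against 0.66 to 1.51 (exact permutation test, p = 0.0286, the smallest possible).

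Osteocyte genes, those of the cells embedded in bone, showed 7 of 13 members falling and 0 rising (10 and 1 adjusted over the list alone), among them Dmp1, a mineralisation regulator, from 180 ± 40.1 to 50.1 ± 24.4 FPKM, and Fbln7, from 2.7 ± 0.616 to 0.6 ± 0.239. The median log2 fold change was -1.74, with an adjusted p of 0.211 with an estimated correlation. The count of 7 was 3 without control 1, 2 without control 2, 4 without control 3, 2 without control 4, 3 without KO 1, 4 without KO 2 and 3 without KO 3. In the fibrillar matrix and periosteum list 11 of 20 fell (15 adjusted over the list alone), including Col3a1 (log2 fold change -2.82), Col5a2 (-2.63) and Bgn (-1.36). Its median was -1.42, with an adjusted p of 0.0814 with an estimated correlation, and 7 members fell without KO 3. Of 14 chondrocyte genes 6 fell (6 adjusted over the list alone), with a median of -1.36 and an adjusted p of 0.0814 with an estimated correlation; 3 fell without control 3 and 3 without control 4.

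The fixed list of osteoclast genes, those of the bone-resorbing cells, did not pass camera as a list. Of 20 members 1 rose and 1 fell (1 and 2 adjusted over the list alone), with a median log2 fold change of -0.14 and a camera adjusted p of 0.4. Mmp14 fell from 34.6 ± 5.34 to 17.6 ± 3.09 FPKM; this membrane protease is also made by osteolineage cells. Mmp9, which neutrophils also make, rose from 409 ± 88.7 to 671 ± 133 FPKM and lost its call without control 1, control 3, control 4, KO 1 or KO 3 (edgeR adjusted p up to 0.0887). Without KO 1, 2 members of the list fell.

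Among signalling lists, Wnt targets had 3 of 16 members falling (4 adjusted over the list alone), median -0.44. Wif1, a secreted Wnt inhibitor, fell from 29.4 ± 6.49 to 10.1 ± 3.75 FPKM; Twist1 and Ccn4 also fell, but lost their calls without control 2, control 3, control 4 or KO 3, and Twist1 also without KO 1 (edgeR adjusted p up to 0.063 and 0.0615). The list's adjusted p was 0.143 with an estimated correlation, and 1 member fell without control 2, control 3, control 4 or KO 3 and 5 without KO 4. Of 16 BMP and TGF-beta targets, 4 fell and 2 rose (7 and 2 adjusted over the list alone), median -0.32, with an adjusted p of 0.311 with an estimated correlation. Ltbp2 (log2 fold change -1.35) and Id3 (-1.11) fell while Id2 rose (0.95), the last lost without control 2 or control 4 (edgeR adjusted p up to 0.0525). The list itself did not pass camera without KO 1 (adjusted p = 0.058) or with limma on log2(FPKM + 0.5) (adjusted p = 0.0534). In that list 2 fell without control 2 and without control 4, and 0, 1 and 0 rose without control 2, control 3 and control 4. Of 16 marrow niche factors 1 fell (1 adjusted over the list alone), Igf1, an insulin-like growth factor, from 3.42 ± 0.368 to 1.96 ± 0.244 FPKM. The median of that list was -0.40 with an adjusted p of 0.311 with an estimated correlation, and 2, 2 and 4 members fell without control 1, KO 2 and KO 4.

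The submitters' text says that osteogenesis related terms were selected. The Gene Ontology terms tested here were instead taken by the name rule, and were lower where they passed. Of 185 terms that met the rule 50 could be tested, and 17 passed camera at the preset correlation, all 17 downwards. With an estimated correlation 0 of the 50 passed, the smallest adjusted p being 0.0635, and 13 had an unadjusted p under 0.05. Ossification had 19 of 53 members falling and 3 rising (median log2 fold change -0.85), and skeletal system development 19 falling and 1 rising of 53 (-1.03). The name rule also took in 27 terms on the cytoskeleton or muscle, of which 0 passed.

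Neutrophil genes were higher in KO. Of 18 members 12 rose and 0 fell (15 rose adjusted over the list alone), with a median log2 fold change of 0.77 and an adjusted p of 0.136 with an estimated correlation. S100a8, a calcium-binding alarmin, rose from 6730 ± 1110 to 12100 ± 1230 FPKM, Cd177, a neutrophil surface protein, from 286 ± 69.2 to 598 ± 35.4, and Ctsg, a granule protease, from 222 ± 29.6 to 367 ± 61.8. The count of 12 was 7 without control 2, 7 without control 3 and 6 without KO 3. Stefin genes, intracellular cysteine protease inhibitors clustered on chromosome 16, supplied 6 of the 10 largest rises: Stfa2 (4.53), Cstdc5 (4.02), Csta2 (3.49), Stfa1 (3.46), Cstdc6 (3.14) and Stfa3 (3.08). Values of single stefin genes are uncertain because paralogs can share reads, and Csta2 lost its call without control 3 or control 4 (edgeR adjusted p up to 0.0761). Mir142 had 1 or 2 counts in the control libraries and 66 to 160 in the KO libraries. The floor covers only genes with at most 12 counts in every library, so it does not apply to Mir142. The fold change of Mir142 would still rest on those 1 or 2 counts and is not given. Its host gene Mir142hg rose (5.42), but both overlap Mir142b on the opposite strand, so with an unknown strand setting their values are uncertain. The summed counts of the 3 genes ran from 396 to 460 in control and from 2165 to 4129 in KO. Il1r2, a decoy receptor for interleukin 1, rose (3.25) with 544 FPKM in KO 4 against 54.8 to 61.5 in the other KO libraries and 16.3 to 25.3 in control; its call was lost without any 1 of the control libraries or KO 3 (edgeR adjusted p up to 0.111).

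B cell genes were lower, 5 of 14 falling (5 adjusted over the list alone) with a median of -0.48 and an adjusted p of 0.311 with an estimated correlation. Dntt and Vpreb1, of early B cells, fell by 2.11 and 2.37 on the log2 scale, and Ebf1, a B lineage factor, by 0.71. Levels of Dntt and Vpreb1 were low, with means of 0.911 and 0.812 FPKM in control and 0.201 and 0.15 in KO. The count of 5 was 2, 2, 0 and 1 without control 1 to 4 and 2, 3, 1 and 3 without KO 1 to 4. Dntt lost its call without any 1 library but KO 2 and KO 4, Vpreb1 without any but KO 2, and Ebf1 without any but control 1 (edgeR adjusted p up to 0.0818, 0.114 and 0.114).

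Interferon response genes were lower in all 20 cases by fitted fold change, and 8 of the 20 fell (14 adjusted over the list alone), median -1.05, with an adjusted p of 0.311 with an estimated correlation. Bst2, a restriction factor, fell from 92.2 ± 17.5 to 35 ± 4.99 FPKM and Ifi44 from 1.1 ± 0.363 to 0.187 ± 0.0723. The count of 8 was 2 without control 2, control 3 or KO 3, 4 without control 4 and 5 without KO 2. Endothelial genes had 3 of 14 falling (7 adjusted over the list alone), Tie1, Cldn5 and Kdr, median -0.46, with an adjusted p of 0.51 with an estimated correlation; 0 fell without control 2, control 3, control 4 or KO 3, and 1 without KO 1 or KO 4. Their edgeR adjusted p reached 0.0915, 0.0898 and 0.111 with 1 library left out.

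Mitochondrially encoded genes had 2 of 13 falling (12 adjusted over the list alone), mt-Nd2 and mt-Nd4l, median -0.94, with an adjusted p of 0.51 with an estimated correlation. That count was 12 without control 1 and 0 without any other single library, with edgeR adjusted p up to 0.109 and 0.0953. The mitochondrial share and the skeletal muscle score were both highest in control 3, at 16.1% and 2.68, and next in control 4, at 11.7% and 1.97. They did not run together elsewhere. KO 2 had a muscle score of 1.46 but the lowest share, 5.56%, and control 2 had the lowest muscle score, -2.32, with a share of 9.21%.

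The 12 lists that passed camera at the preset correlation were those with an estimated-correlation p above, 11 down and 1 up, and 0 of the 29 passed with an estimated correlation, where 6 had an unadjusted p under 0.05. With fry, 2 lists passed upwards and 10 downwards. Splitting the 8 libraries in other ways also gave many such lists, 12 or more in 17 of the 35 possible splits with the real one counted, so the number of lists does not set the genotype apart. The exact test of list scores reached its smallest p, 0.0286, for 10 of 29 lists, and 0 passed after adjustment (smallest adjusted p = 0.0829).

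Other lists did not pass camera. Nuclear oxidative phosphorylation had 2 of 60 genes rising (1 adjusted over the list alone), Ndufv3 and Ndufb7, median -0.06; 1 rose without control 1, control 2, control 3, control 4, KO 1 or KO 3. Ndufb7 was lost without any 1 library but KO 4 (edgeR adjusted p up to 0.126). This list passed camera downwards after quantile normalization of log2(FPKM + 0.5) (adjusted p = 4.89e-06). Of 15 RIP kinase and necroptosis genes 2 rose (2 adjusted over the list alone), Sharpin (0.57) and Tnfrsf1a (0.46), with a median of 0.17, a camera adjusted p of 0.12 and a fry adjusted p of 0.0435. That count was 1 without control 1, control 3, control 4 or KO 1 and 0 without control 2 or KO 3, with edgeR adjusted p up to 0.0558 for Sharpin and 0.133 for Tnfrsf1a. The list passed camera upwards with no filter on low values (adjusted p = 0.0476).

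Of 18 NF-kB and cytokine genes Nfkbia rose and Cxcl10 fell (1 and 1 adjusted over the list alone); Nfkbia was lost without control 1, control 2, control 3, control 4, KO 2 or KO 3, and Cxcl10 without any 1 library but control 4 (edgeR adjusted p up to 0.133 and 0.102). Without KO 4, 2 members of the list rose. The median of this list was 0.10. In the unfolded protein list Pdia4 fell, 1 of 16 (1 adjusted over the list alone), with a median of -0.16; it was lost without any 1 library but KO 1 and KO 4 (edgeR adjusted p up to 0.0852). In the immediate early and heat shock list Hsph1 fell, 1 of 16 (1 adjusted over the list alone), with a median of -0.33, and 2 fell without KO 4. Of 24 proliferation genes 0 passed (0 adjusted over the list alone), with a median of 0.13, but that list passed camera upwards without control 1 (adjusted p = 0.00546).

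Skeletal muscle genes varied widely between libraries of both groups. All 18 had a lower fitted value in KO, median -1.20, but 0 passed (0 adjusted over the list alone; camera adjusted p = 0.197). The list passed downwards without control 1 (adjusted p = 0.0402), control 2 (0.000365) or KO 2 (0.0186). The muscle score was 2.68 in control 3, 1.97 in control 4 and 1.46 in KO 2, and between -2.32 and 0.27 in the other 5 libraries. Pvalb, a calcium buffer of fast muscle, had 325 FPKM in control 3 and 8.68 in control 2. Of 12 stem and progenitor genes Cd34 and Meis1 fell (4 fell and 1 rose adjusted over the list alone; median -0.04), with 1 falling without control 1, KO 1 or KO 4 and 0 without any other library (edgeR adjusted p up to 0.124 and 0.115).

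Of 14 keratinocyte genes Sfn, a 14-3-3 protein, rose from 8.28 ± 1.41 to 19.1 ± 3.87 FPKM (1 adjusted over the list alone; median -0.29). The score of this list was -3.07 in KO 1 and 0.22 to 0.90 in the other KO libraries. No adipocyte (median -0.21), erythroid (-0.11, with a mean of 0.11 and a camera direction up), T and NK cell (-0.08), monocyte and macrophage (-0.31), megakaryocyte (-0.09) or eosinophil, basophil and mast cell gene (-0.18) passed, 0 in each list over all genes and 0 adjusted over the list alone. The erythroid list passed camera upwards without control 1 (adjusted p = 0.0162) and the monocyte and macrophage list downwards without KO 1 (adjusted p = 0.0181).

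**Figure D2:**
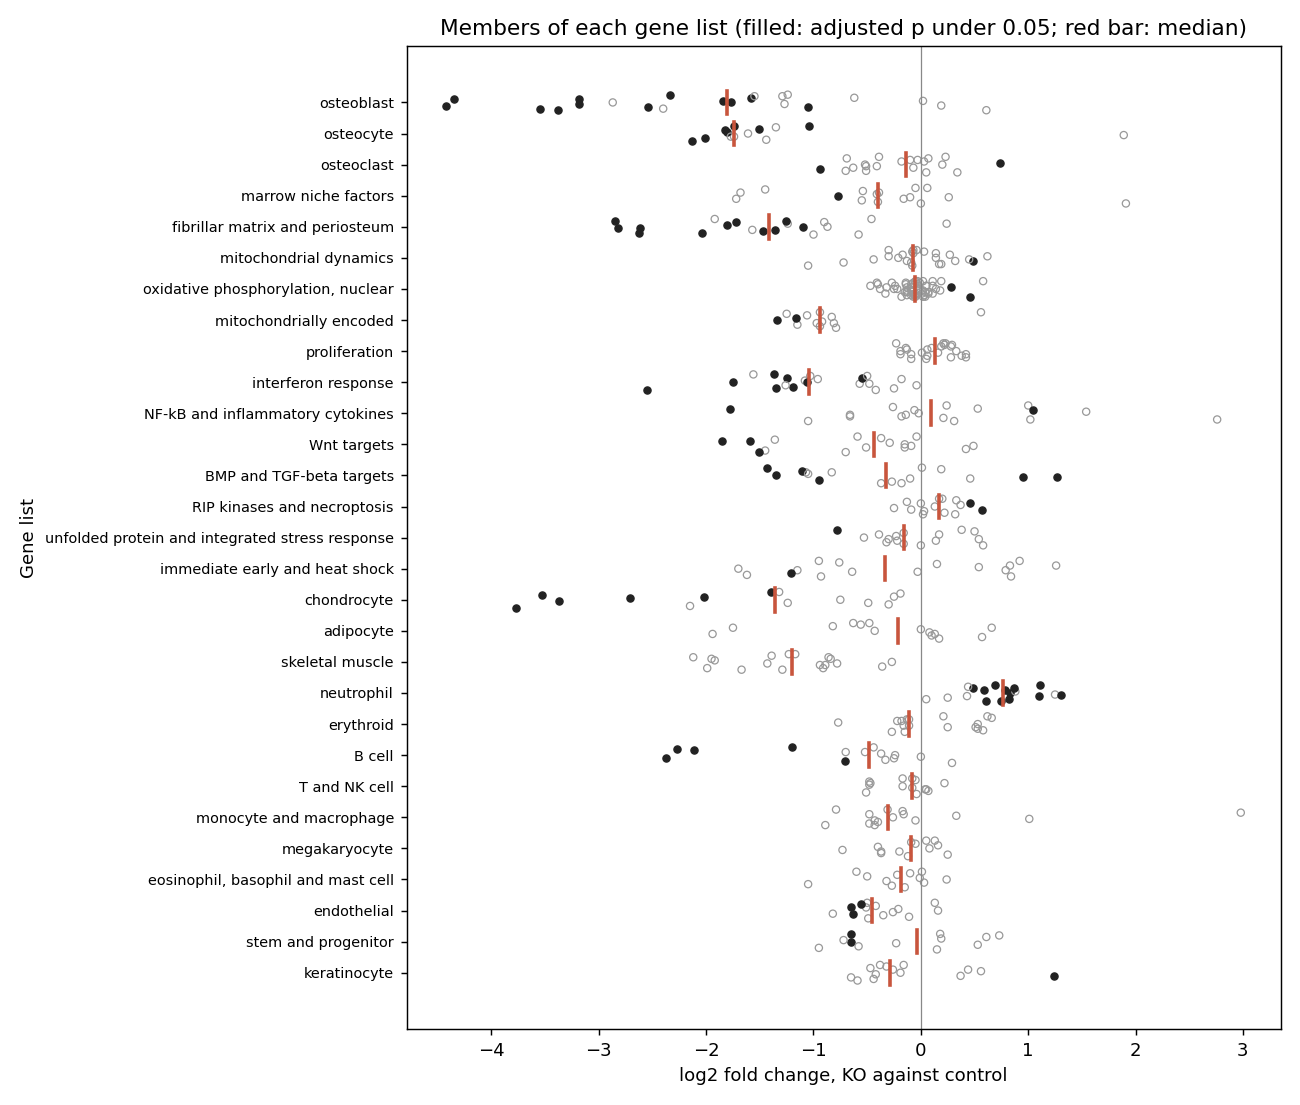
log2 fold change of KO against control for every tested member of the 29 lists (points, filled where the edgeR adjusted p is under 0.05), with the list median as a red bar. Osteoblast genes have a median of -1.80 and neutrophil genes one of 0.77, while osteoclast genes centre at -0.14.

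**Figure D3:**
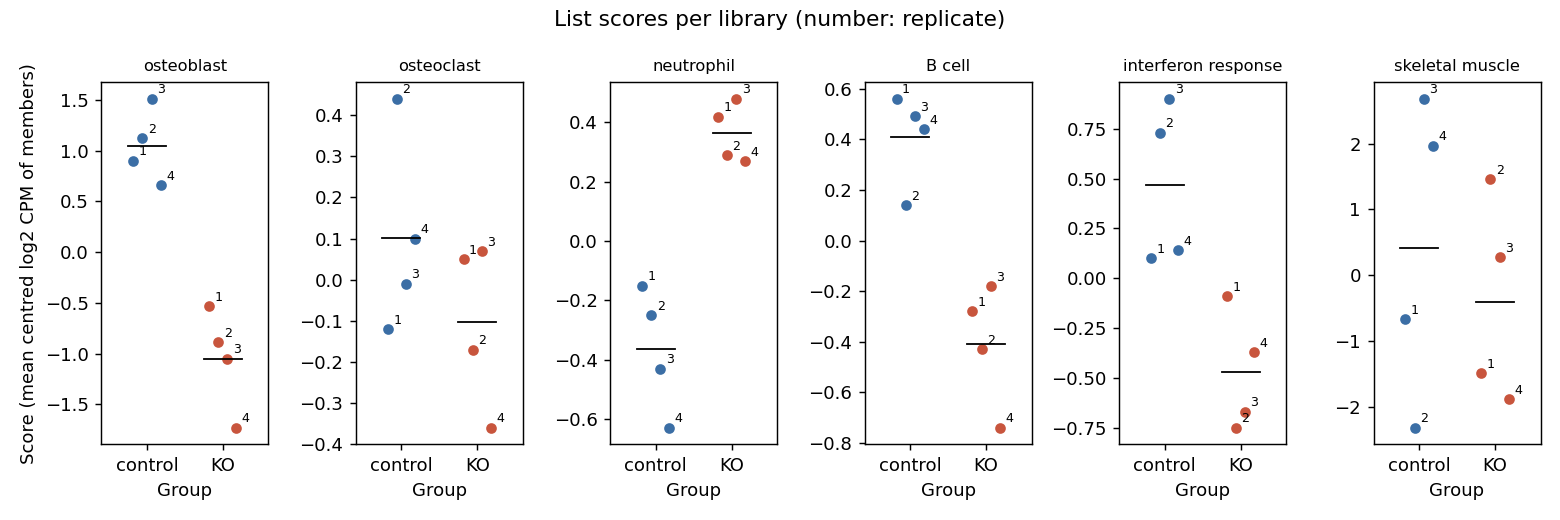
Score of 6 lists in each library (points, numbered by replicate; the score is the mean centred log2 CPM of the members), with the group mean as a bar and a separate axis range per panel. The osteoblast score is 0.66 to 1.51 in control and -1.73 to -0.53 in KO, while the muscle score overlaps between groups.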

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

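The tests of bone tissue, muscle, stefin paralogs, neutrophil number and macrophages were chosen after the results they bear on were seen; those of GC content and length were not.

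Each group of 4 was examined for a library far from the rest, by its gap to the nearest library over the group's range; 19 of 208 groups passed, where chance gives about 1 in 20, or 10. In KO 4, Il1r2 stood at 544 FPKM (others 54.8 to 61.5), Mmp14 at 13 (19.1 to 19.4), Ifi44 at 0.0801 (0.212 to 0.24), Ccn4 at 1.35 (5.01 to 6.01) and the stem and progenitor score at 0 (-0.1 to -0.09). In KO 1, Col1a1 stood at 374 FPKM (125 to 147), Col1a2 at 156 (76 to 85.6), Igf1 at 2.32 (1.8 to 1.87), Bst2 at 42.5 (31.8 to 33) and the keratinocyte score at -3.07 (0.22 to 0.9). Ebf1 was 1.19 FPKM in KO 3 (1.31 to 1.32). In control 3, Fbln7 stood at 1.78 FPKM (2.99 to 3.04), Cldn5 at 23.2 (18.4 to 18.9) and Adgre1 at 10.1 (13.9 to 14.3). In control 4, Cstdc6 stood at 0.611 FPKM (0.413 to 0.436) and Bgn at 152 (204 to 211). Mir142 was 0.259 FPKM in control 2 (0.011 to 0.043), which are counts of 2 against 1 in each of the others, too few for a measurable difference. In control 1 Id2 was 26 FPKM (24.2 to 24.4) and the BMP and TGF-beta target score -0.06 (0.26 to 0.31).

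The fall of osteoblast genes was weighed against 3 technical sources. Less bone or cartilage in the KO pieces stays open, since the osteocyte score (-1.64), the fibrillar matrix and periosteum score (-1.55) and the chondrocyte score (-1.78) changed about as much as the osteoblast score (-2.09), while the neutrophil score changed by 0.73. The osteoclast score went against it, with a change of -0.2 that left a difference of -1.89 (exact permutation p = 0.0286, the smallest possible). The osteoblast score alone already gave that p, so the p adds nothing on this question. Of the 20 osteoclast genes 13 were lower in KO and 7 higher. Among the lower ones Ctsk and Acp5, chosen after their values were seen, had log2 fold changes of -0.70 and -0.39 without passing. The median of the osteoblast list was -1.85 with the muscle score in the fit and -1.77 after removal of a trend on GC content and length, against -1.80 before, so neither accounts for it. Fewer osteoblasts, less matrix expression per cell, and an effect of Ripk4 loss, of Cre or of another difference between the mice also stay open and were not tested.

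The rise of stefin genes was weighed against 2 sources. Reads moved between paralogs would leave the family's sum unchanged, but the summed counts rose by 3.14 log2 units, from 71.9 ± 19.9 to 623 ± 121 CPM. More neutrophils of unchanged makeup would raise both scores alike, but the stefin score was 1.82 further above control than the neutrophil score (2.55 against 0.73); the family was picked for its rise, so no p is given for either value. A change of state within neutrophils or another stefin-expressing cell remains a hypothesis, and a sequence variant in the chromosome 16 cluster that differs between the mice was not tested.

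The fall of interferon genes was weighed against 2 sources. The interferon score fell by 0.94 and the monocyte and macrophage score by 0.18, a difference of -0.76 (exact permutation p = 0.0286, the smallest possible). The interferon score alone already gave that p, so the p adds nothing on this question. Of the 15 monocyte and macrophage genes 3 were higher and the others lower, with a median of -0.31 and an SD of 0.95 over members. Fewer macrophages thus stay open. Among the lower genes Adgre1 was at -0.79 and Ms4a7, chosen after its value was seen, at -0.89, neither past the threshold. The 3 higher genes were Ccr2 (1.01), Ly6c2 (0.33) and Cd14 (2.98), also not past the threshold. Cd14 ranged from 5.02 to 147 FPKM in KO. Removal of the GC and length trend left the median of the interferon list at -0.98, from -1.05, so such a trend does not account for it. A difference in interferon exposure between the mice stays open and was not tested.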

How the results depend on the processing

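The alternatives that left libraries out together, counts divided by 4, the muscle covariate and terms without cytoskeleton or muscle names were chosen after seeing the data.

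The number of genes changed, 2083, was 56 with the replicate block, of which 55 were shared; same-numbered libraries did not deviate together (correlations 0.11, -0.17, 0.09 and -0.06), and only control 1 matched its own number best, so the numbers do not pair the samples. It was 4189 with DESeq2, 3965 without its filter and 3805 with the block, and 800 with at least a 2-fold change required. With libraries left out it was 769 to 2230 for each in turn, 1323 for control 3 and KO 4, and 23 for control 3, control 4 and KO 2. The 2-fold requirement removes genes by construction, and leaving libraries out shrinks the groups, which can by itself lower the count. The cause of these changes was otherwise not tested. The count was 1469 with the muscle score as a covariate and 2500 with counts divided by 4. Limma on FPKM gave 1795 to 1939 over the pseudocounts. Other filters, scalings, library weights and robust estimation gave 1465 to 2472. Gene lists changed numbered 12 to 15 and osteogenesis terms 14 to 18 with each library left out, and 0 of either with an estimated correlation; osteogenesis terms numbered 10 with a filter of 2 FPKM and 11 with terms of 10 to 200 members, which leave fewer terms. Of the 35 splits of the libraries into 4 and 4, 1, the real one, gave 2083 genes, and the highest other gave 5. A share of 1 in 35 is the smallest this test can return, and it was not adjusted for the several counts compared. Chance is thus made less likely for genes, within these libraries, but is not excluded. For lists, 17 splits gave 12 or more, with up to 17 in another split, so chance cannot be excluded. Only the real split gave 17 osteogenesis terms, with 12 the highest other. The same limit holds there, and 0 of these terms passed with an estimated correlation. For Ripk4, whose levels all lie at or under the floor, the statistic of the permutation test is set by the pseudocount and is no fold change; it was -0.02, -0.08 with a pseudocount of 0.1, 0 without control 1, and -0.05 to 0 with each library left out. Mfn2's difference of 0.16 was 0.07 to 0.21. Of the 133 genes of the naming rule 70 passed; 71 of them, besides Ripk4 and Mfn2 and picked mostly for having passed, were run under the alternatives, and of their 66 calls 9 held under all 25 settings, 57 were lost under at least 1 and 0 reversed, and 38 of the 66 held with any 1 library left out. Few calls could hold under all settings. The replicate block called 56 genes, and the omission of control 3, control 4 and KO 2 called 23. Of the 2083 calls that omission kept 14, so the 57 losses do not measure how calls fared under the other settings. The median log2 fold change of all genes stayed between -0.03 and 0.02. Depth limits what can be said of Ripk4.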

Other observations

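The tests and genes in this part were chosen after the data were seen. Among 2428 Gene Ontology and KEGG terms, 35 passed camera upwards and 117 downwards, and 0 with an estimated correlation, where 126 had an unadjusted p under 0.05. Collagen fibril organization had 19 of 31 members falling, and cellular response to interferon-beta 11 of 36. Upwards, cysteine-type endopeptidase inhibitor activity had 9 of 23 rising, defense response to bacterium 14 of 140 and immunoglobulin receptor binding 8 of 101, the last while genes of early B cells were lower. The KEGG term osteoclast differentiation also passed upwards (adjusted p = 0.00527; adjusted p = 0.845 with an estimated correlation), with 17 of 112 members rising and 2 falling.

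The family of stefin genes on chromosome 16 has 11 members in the table, of which 10 were tested and 8 rose, with a median log2 fold change of 3.11. The 2 others tested were Csta1 (-2.06 ± 1.14) and Csta3 (0.94 ± 0.58), neither past the threshold.

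At the Mir142 locus, the summed estimated counts of Mir142, Mir142hg and the opposite-strand Mir142b ran from 396 to 460 in control and from 2165 to 4129 in KO. Mir142b alone held 347 to 416 in control and 551 to 1444 in KO. The rise is thus present in the sum, which does not depend on how reads were divided among the 3 genes.

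Keratin genes were missing or low in 1 library. Krt5 had 0 counts in KO 1 and 318 to 582 in the other 7 libraries, Krt14 0 against 493 to 956, Krt1 0 against 270 to 555, Krt15 0 against 97 to 189, and Krt10 57 against 270 to 433.

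A hypothesis was that the rise of neutrophil genes was larger for genes of late than of early stages, from 8 late and 7 early genes listed before the test but after fold changes of neutrophil genes had been seen. The late score rose by 0.85 and the early score by 0.51, and the difference of 0.34 did not exceed the spread (exact permutation p = 0.371), so the data may hold such a difference but do not show it.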
